A study of Mus musculus with 6 samples.

How the data were processed

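RNA of 6 subcutaneous Hepa1-6 tumors was measured on 2-colour Agilent arrays, 1 array per tumor. Per the labels, tumor RNA carried Cy5 on every array and the reference, total RNA of blood of an untreated C57Bl/6 mouse, carried Cy3. No dye swap was made, so a dye bias of a probe stays in its ratio. The labels put 3 tumors at day 10 after inoculation (302, 307 and 312) and 3 at day 15 (303, 313 and 318), and tumors are named here by these numbers. The labels do not say which mouse each tumor came from, so p-values measure the spread between these tumor samples.

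Per the file headers, the deposited scanner output was made with Agilent Feature Extraction 9.1.3.1. It holds, for each spot and dye, the mean pixel intensity and the median intensity of the local background, neither of them normalized. Per the file headers, the processed intensity of each spot had already been background-subtracted with spatial detrending, detrended multiplicatively and dye-normalized with LOWESS by that software. The log ratio in the deposited scanner files is the log10 of processed Cy5 over processed Cy3. It is 0 where both dyes hold a surrogate for a signal not above background, which was so for 24.3% to 29.6% of spots per array. The value table deposited by the authors holds log10 ratios that differed by 0 from this scanner log ratio at every spot, so its scale, direction and centring are those of the software. The median of each of its columns was 0. Flags of the software (well above background, saturated, non-uniform or population outlier) were used as deposited.

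Each array held 45018 spots, of which 1639 were controls. The other 43379 spots carried 41174 probes, 245 of them printed 10 times. In limma 3.58.1 under R 4.3.3, mean intensities were background-corrected with normexp and an offset of 50. The log2 ratios were normalized within each array by loess, with control and outlier spots at weight 0. Control spots and spots with an outlier mark (45 to 71 per array) were then left out, and spots of a probe were averaged. Saturation touched at most 1 spot per array and no gene named by the rule given further on. Probes were named through a mouse RefSeq gene table (assembly GRCm38.p6). Of the 41174 probes, 23374 were named by accession, 6733 by current symbol and 2919 by an older symbol, and 8148 kept the name printed in the array files. Because the array files name no genome build, no coordinates are given. A gene was represented by its probe with the highest mean log intensity. Some listed genes had no probe under that name, among them Ly6g, Pck1 and H2-D1.

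Day 15 tumors were compared with day 10 tumors on 23055 probes (15791 genes) well above background in Cy5 on at least 3 of the 6 arrays. The comparison used limma's lmFit and eBayes, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 6 tumors were compared with the reference as the average of both day means against 0, on 24214 probes (16297 genes) well above background in either dye on at least 3 arrays. There an absolute log2 ratio of at least 1 was required as well. This test leaves out the spread between blood samples, since the reference was the same description of RNA on every array. As a check on the slides, the Cy3 signal was compared between the arrays of the days on 20915 probes after quantile normalization.

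For a gene not well above background on any array of a group, the ratio is given as a bound, "at least N-fold". The brighter side's mean was set against, on each array, the higher of the dim probe's own signal and the lowest signal among probes well above background. This was not given where another probe of the gene was well above background. These bounds used each dye's signal after loess and Aquantile scaling and stay open to dye bias without balanced swaps. Gene lists of cell types and pathways, 31 in all, were tested with limma's camera at a preset correlation between genes of 0.01. An estimated correlation and the rotation test fry served as alternatives. Fry's test asks whether the genes of a list move on balance in a common direction, and does not set the list against other genes.

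Tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per direction, the 12 genes of largest change between the days past the threshold with values of the days apart, filled up with the genes of smallest p where fewer passed. It added up to 4 genes of smallest p in each list. Against the reference it took the 10 highest and 10 lowest genes past the threshold with the same sign on all 6 arrays, and 3 genes of largest absolute ratio in each of 7 lists. Genes named only as a clone, an accession or a gene model were passed over. Other names in the text were chosen after their values were seen, and are said to be.

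All day 10 arrays lay on 1 slide and were scanned together, and all day 15 arrays lay on another. Slide and day therefore cannot be told apart, and no model with the slide as a block could be fitted. Array position on the slide could be entered as a block. Alternatives covered the normalization, background correction, processed signals, value table, filter, outlier spots, variance prior, tumor channel alone, position block, choice of probe, minimum change and each tumor left out in turn. After the data were examined, 1 more was added, in which spots lying in an area of lost reference signal were left out. An area was defined by windows of 7 by 7 spots in which at least 0.25 of the spots had Cy3 signal 1 or more log2 units under the mean of the other arrays.

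The procedure was tested on simulated data with the spread of the real arrays over 22873 probes for the comparison of the days. Of 200 genes changed by a log2 of 1, 2 and 4, it recovered 0%, 72.5% and 95% respectively. There were no calls at a log2 of 1, and at 2 and 4 the share of unchanged genes among its calls was 3.97% and 6.40%. With a list of 22 genes shifted by 0.5, camera called that list and 1 of the other 30. Genes were drawn independently of each other there. In the real lists the estimated correlation ran from -0.04 (platelet and megakaryocyte genes) to 0.87 (cell cycle genes). The simulation therefore cannot show how often camera calls unchanged lists in these data. The number of arrays, 3 per day, limits the precision of every comparison.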

Results

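The series measured gene expression in tumors that grew after cells of Hepa1-6, a mouse hepatoma line, were placed under the skin of female C57Bl/6 mice. Tumors were removed at day 10 (n = 3) or day 15 (n = 3), and each was hybridised with the reference RNA labelled as blood of an untreated mouse. Between 52.4% and 58.5% of spots per array were well above background in the tumor channel, and 47.5% to 52.8% in the reference channel. The median tumor signal ranged from 198.0 on the array of tumor 312 to 309.5 on that of tumor 302. Across probes, the log2 ratios of any pair of arrays correlated with r from 0.847 to 0.985, a description across genes and not across replicates.

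On the array of day 10 tumor 312, an oval area in the centre had lost signal. It held 13.9% of the spots, lay between rows 155 and 357 and columns 23 and 65, and covered 3238 probes tested between the days. The Cy3 signal of this array correlated with that of the other arrays at 0.825 to 0.839, against at least 0.993 among those, and at 0.984 to 0.991 over the spots outside the area. Genes with probes there, among them S100a9, Cd8b1, Lyve1, Fmod, Arntl, Dbp, Eno1 and H2-DMa, had a less secure value in this tumor.

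**Figure D1:**
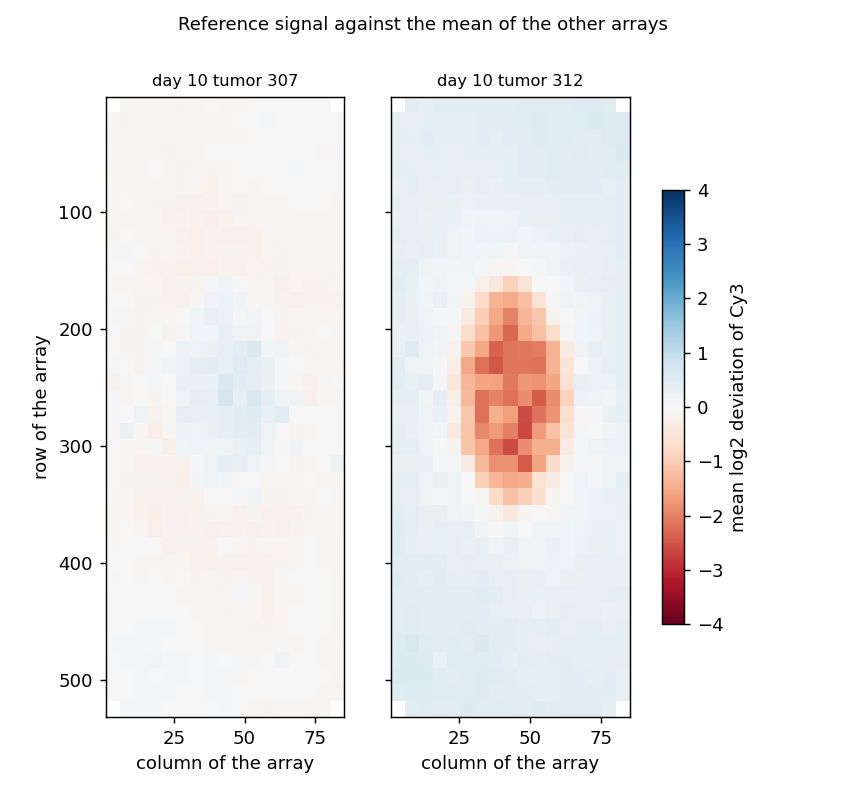
Mean log2 deviation of the reference (Cy3) signal from the mean of the other arrays, by row and column of spots, for day 10 tumors 307 and 312. The array of tumor 312 holds a central area with 13.9% of the spots in which the signal was low, and that of tumor 307 holds none.

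The comparison of tumor with the reference asked which genes tumor tissue expressed above or below the blood RNA named in the labels. Genes of macrophages, matrix and vessels stood highest in the tumors. Ctss, a lysosomal protease of macrophages, had a log2 ratio of 10.30 ± 0.30 (SD, n = 6), Clec7a, the beta-glucan receptor dectin-1, 8.62, and Adgre1, which encodes the macrophage marker F4/80, 8.36. Lum, Sparcl1, Cav1, Ppic and Srgn, the last a proteoglycan of blood and endothelial cells, lay between 7.85 and 8.53. The collagen chaperone gene Serpinh1 reached 7.66, Col1a1 7.65 and Col3a1 7.05. Ptprc, the pan-leukocyte gene encoding CD45, was higher as well, but 3 of its 4 probes, the one standing for the gene included, were not well above background in the reference on any array, so no size is given. Clec7a was above background in the reference on 2 of 6 arrays and Lum on 1, so the size and order of their ratios are less secure.

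In all, 4157 genes were higher in tumor and 1593 lower, so that 72.3% of the calls were higher (limma, Benjamini-Hochberg adjusted). This split depended on the scaling. It was 3239 higher and 4587 lower (41.4% higher) after median centring without loess, which moved the median ratio of all genes from 0.22 to -0.34. With the scanner's processed signals it was 4445 and 3232 (57.9%), and with the values of the authors, 4450 and 3230 (57.9%). Of the 4157 genes, 3876 were above 0 on all arrays.

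Most cell-type lists lay on the tumor side. Of the genes tested, 26 of 27 macrophage and monocyte genes, 28 of 30 collagen and matrix genes, 20 of 23 fibroblast and pericyte genes and 19 of 23 endothelial genes were higher, with Cdh5 (VE-cadherin) at least 36.1-fold and Lyve1 at least 37.3-fold higher, neither gene being well above background in the reference with either of its 2 probes. Lymphocyte genes did the same: 20 of 21 T cell genes, such as Cd3g at 5.25, all 21 NK and cytotoxic lymphocyte genes and 12 of 15 B cell and plasma cell genes. Hepatocyte and hepatoma genes were higher in 15 of 28 and lower in 2. Among them were Gpc3, a glypican of liver tumors, at 5.03, Ambp at 6.01 and the prothrombin gene F2 at 4.51. Tumor 313 lowered the means of Ambp and F2, which were 7.41 and 5.38 over the other 5 tumors. Cell cycle genes were lower than the reference in 27 of 39, cholesterol synthesis genes in 11 of 22 and skin epithelium genes in 4 of 10, and none of these 3 lists held a higher gene at this threshold. The lowest ratios belonged to H60, a ligand of the NK receptor NKG2D, at -4.76 ± 0.16 (SD, n = 6), the milk protein gene Csn3 at -4.24, Magea6 at -4.13, the mucin gene Muc16 at -3.70 and the homeobox gene Rhox5 at -3.25.

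**Figure D2:**
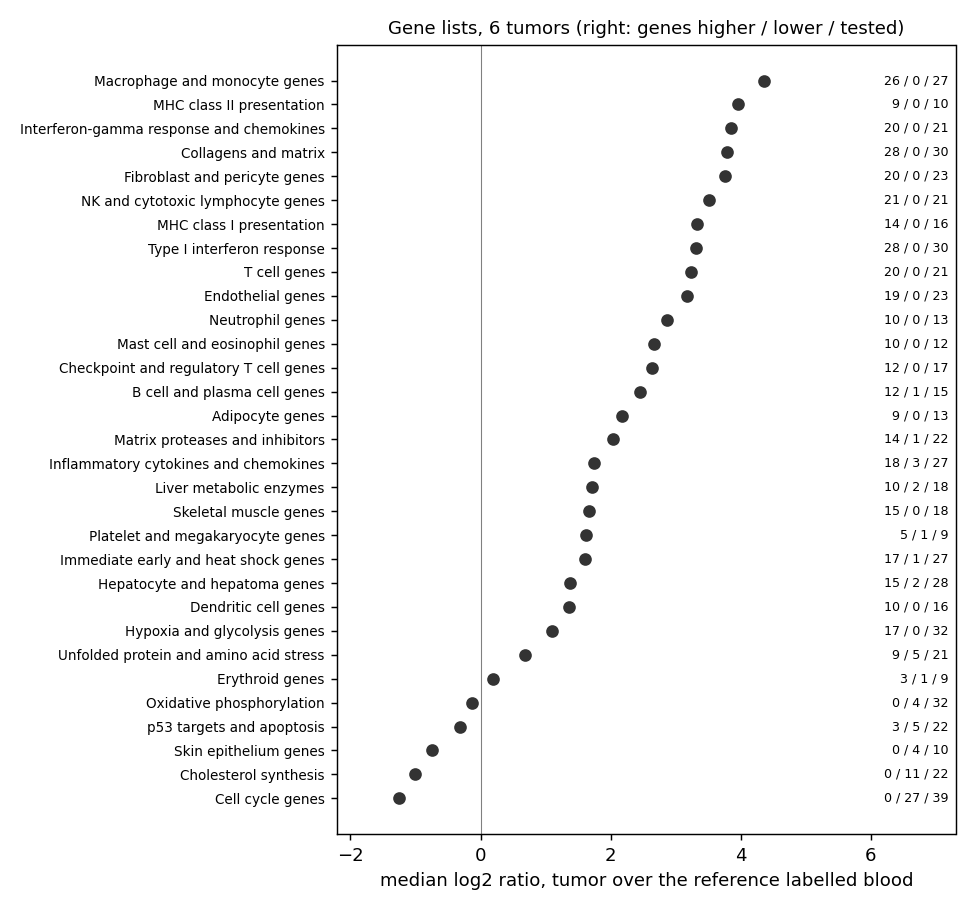
Median log2 ratio of tumor over the reference labelled blood for each of 31 gene lists over all 6 tumors (horizontal axis), with the number of genes higher, lower and tested at the right. The macrophage list stands highest with 26 of 27 genes higher, and the cell cycle list lowest with 27 of 39 lower.

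The reference channel itself held little signal for several leukocyte genes. Of 28 probes of neutrophil genes, 1 was well above background in Cy3 on all 6 arrays. S100a8, a neutrophil calcium-binding protein gene, was above background in Cy3 on 0 arrays. Over whole lists the picture was mixed: 63.3% of probes of abundant blood cell genes, 55.8% of macrophage probes and 33.3% of probes of further hepatoma genes were above background in Cy3 on all arrays, against 42.9% of all probes. The liver and epithelial genes Alb, Afp, Foxa2, Krt8 and Krt18 were well above background in Cy3 on all 6 arrays, as was Rhox5. These genes were chosen after their values were seen. Hemoglobin genes were also higher in tumor, with Hbb-bt at 5.80 and Hba-a1 at 3.76. Directions against this channel are therefore given as against the reference labelled blood.

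Tumor 313 of day 15 stood apart in liver and hepatoma genes. Its log2 ratio was -0.99 for Ambp, where the other 5 tumors lay between 7.17 and 7.93, and 0.15 for F2, where they lay between 5.08 and 6.00. The alpha-fetoprotein gene Afp differed from the mean of the others by -7.33, the albumin gene Alb by -5.20 and the liver transcription factor gene Foxa2 by -5.45. Krt8 and Krt18, keratins of simple epithelia, differed by -2.72 and -2.23. Rhox5 (+0.29), Hmga1 (+0.07) and Muc16 (+0.05) differed by no more than the SD of the other 5 tumors. Not every hepatoma gene was low: Gpc3 was at 5.13, and Dlk1, H19 and Cdh1 were highest in this tumor. Its medians of macrophage (4.75), T cell (3.99), endothelial (3.86) and collagen genes (4.46) were the highest of the 6 tumors, and that of neutrophil genes (1.38) was the lowest. Afp, Alb, Foxa2, the keratins, Hmga1, Dlk1, H19 and Cdh1 were chosen after their values were seen. Of 12613 genes well above background in all 6 tumors, 94 lay in this tumor 2 or more log2 units under the lowest other tumor. The number was 26 in tumor 312, whose array holds the area of lost signal, 1 in tumor 303 and 0 in the rest. Ambp and F2, above background in 5 tumors, were not among the genes counted.

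**Figure D3:**
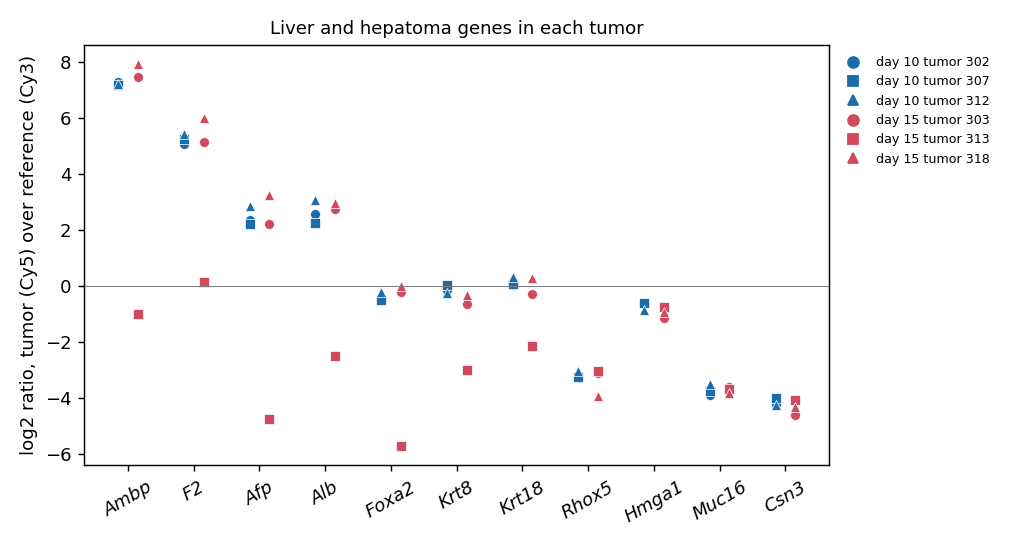
Log2 ratio of tumor over reference for 11 genes in each tumor, with day 10 tumors in blue and day 15 tumors in red (circle, square and triangle for 302, 307 and 312 or 303, 313 and 318). Day 15 tumor 313 lies below every other tumor for Ambp, F2, Afp, Alb, Foxa2, Krt8 and Krt18, among them for Hmga1, Muc16 and Csn3, and just above them for Rhox5.

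The comparison of the days asked how the tumors changed between day 10 and day 15 of growth. The 7 genes that fell were all genes of striated muscle, and 2 genes rose. Myh4, a myosin heavy chain of fast fibres, fell by 4.75 on the log2 scale of the ratio (SE 0.20). In Cy5 signal alone it was at least 290-fold lower, being above background on 3 of 3 day 10 arrays and 0 of 3 day 15 arrays. Its limma adjusted p (Benjamini-Hochberg) was 0.00161. Tnnc2, fast troponin C, fell by 4.42 (SE 0.18, limma adjusted p 0.00161), and Myh8, a perinatal myosin heavy chain, fell by 5.09 (SE 0.28, limma adjusted p 0.00475). Myh1 fell by 3.92, the skeletal actin gene Acta1 fell by 3.67, the myosin-binding protein gene Mybpc2 fell by 3.50 (at least 37.3-fold in Cy5 signal alone) and the titin-cap gene Tcap fell by 3.28. The genes that rose were Igkv14-111, an immunoglobulin kappa variable gene, by 2.35 (SE 0.15, limma adjusted p 0.00926), and a transcript named only LOC56304 on the array, by 2.19 (SE 0.16, limma adjusted p 0.0190), which is outside the naming rule and was named after its value was seen.

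**Figure D4:**
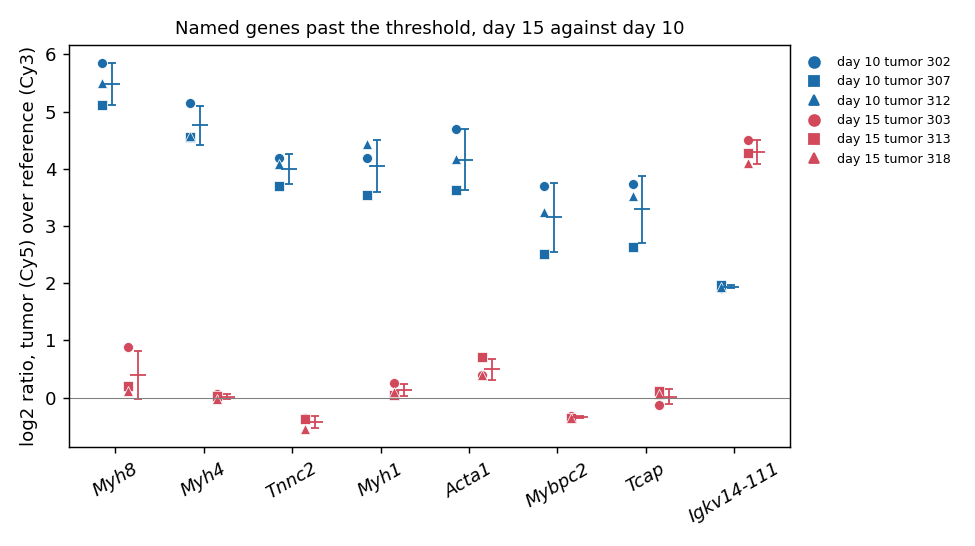
Log2 ratio of tumor over reference for the 8 named genes past the threshold between the days, with each tumor as a point and the mean ± SD (n = 3) beside it. The 7 muscle genes lie between 2.52 and 5.84 in the day 10 tumors and between -0.54 and 0.88 in the day 15 tumors.

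At an unadjusted p under 0.05, 385 genes were higher and 247 lower, a balance that median centring without loess turned to 108 higher and 3590 lower. With loess, 3.54% of probes had such a p-value, a share under the 0.05 that chance gives. In all, 1436 genes (9.09%) had values of the days that did not overlap, where chance gives 10%. In the tumor channel alone, with quantile normalization, 0 genes passed (149 higher and 325 lower unadjusted, smallest limma adjusted p 0.203), so every call was lost there. The reference signal of the muscle genes was not steady, as was seen after the comparison: all 7 genes that fell were also lower in Cy3 at day 15, 6 of them with an unadjusted p under 0.05 and 0 after adjustment. For Myh4 the change was -8.46 (SE 0.84) in Cy5 and -4.72 in Cy3, so that part of the change and much of the spread between tumors left the ratio. Myh1 was uneven within day 15. On the array of tumor 318 its log2 Cy3 signal was 10.32, above the day 10 arrays (8.08, 7.32 and 10.05). On those of tumors 303 and 313 it was 6.30 and 6.10. Its Cy5 change was -4.28 (SE 1.21), so its fall in the ratio does not show lower signal in every day 15 tumor. Of the 18 muscle genes of the fixed list, 16 were lower in Cy3 (median -1.17, against -3.98 in Cy5), and Igkv14-111 was higher in Cy3 by 1.37. The cause was not tested, and the small SE of these ratios rests on both dyes moving together. Without tumor 307 the number of lower genes was 24, without 302 and without 303 it was 3, and without 312 and without 318 it was 4. Without 313 it was 7, of which Myh1, Myh4, Myh8 and Tnnc2 were muscle genes. LOC56304 did not pass without 302, 312, 303, 313 or 318, with a position block, or with the scanner's processed signals or the value table. Igkv14-111 did not pass without 302, 312 or 303, with a position block, after median centring, or with the scanner's processed signals or the value table, where its change was 0.51.

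Skeletal muscle genes of the fixed list moved together. Of 18 tested, 17 had lower values at day 15; 5 fell over all genes, and 16 fell when adjusted over the list alone. The median change was -2.98, with medians per tumor of 3.90, 2.15 and 3.55 at day 10 and -0.02, 0.02 and -0.08 at day 15. The list was lower by camera with an adjusted p of 5.5e-42, but had adjusted p = 0.348 with an estimated correlation; fry gave an adjusted p of 0.0285. Genes that did not pass included the muscle gene Apobec2 (-3.20).

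The lists of vessels and stroma were called higher at day 15 only with camera's preset correlation. Of 22 endothelial genes, 20 were higher (median +0.62, camera adjusted p 2.9e-10, but adjusted p = 0.509 with an estimated correlation), and 12 passed without adjustment but 0 over all genes and 0 when adjusted over the list alone. Cldn5, a tight junction gene, was higher by 1.23 and Emcn (endomucin) by 0.89. Fibroblast and pericyte genes were higher in 20 of 23 (median +0.40, camera adjusted p 5.1e-06, but adjusted p = 0.678 with an estimated correlation), with Tagln, a smooth muscle actin-binding gene, at +1.64; 0 passed over all genes and 1 when adjusted over the list alone. Collagens and matrix genes were higher in 24 of 30 (median +0.31, camera adjusted p 5.6e-04, but adjusted p = 0.678 with an estimated correlation), and 0 passed over all genes and 0 when adjusted over the list alone. The collagen call was lost without tumor 312 or 313.

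Adipocyte genes were higher in all 13 tested (median +1.16, camera adjusted p 2.7e-04), with 0 passing over all genes and 0 when adjusted over the list alone, and adjusted p = 0.678 with an estimated correlation. Fabp4, the fatty acid-binding protein of adipocytes, was higher by 1.41, and Plin1, a lipid droplet protein gene, by 2.68. Plin1 was uneven within day 15, at 5.53 and 5.55 in tumors 303 and 313 and 0.81 in tumor 318. So was the list, with medians of 3.83 and 4.41 in tumors 303 and 313 and 0.86 in tumor 318. That of tumor 318 was the lowest of all tumors, below the day 10 medians of 1.41, 2.23 and 0.94.

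Several immune and blood lists were called higher as well with the preset correlation. B cell and plasma cell genes were higher in 14 of 15 (median +0.67, camera adjusted p 2.3e-07, but adjusted p = 0.509 with an estimated correlation), with 0 passing over all genes and 5 when adjusted over the list alone; Jchain, the joining chain of antibodies, was at +1.89, Mzb1 at +1.86 and Pou2af1 at +1.89. Macrophage and monocyte genes (25 of 27 higher, median +0.23, adjusted p 0.00129), T cell genes (17 of 21, +0.24, 0.00727) and mast cell and eosinophil genes (11 of 12, +0.40, 0.00727) had 0 genes passing over all genes and 0 when adjusted over the list alone. Each of these lists had adjusted p = 0.678 with an estimated correlation. Erythroid genes (7 of 9, +0.26, adjusted p 0.00487) had 2 genes passing when adjusted over the list alone, Alas2, the first enzyme of erythroid heme synthesis, at +1.17 and Hbb-bt at +0.57. Platelet and megakaryocyte genes (7 of 8, +0.28, adjusted p 0.0319) had 0, and both of these lists had adjusted p = 0.509 with an estimated correlation. The macrophage call was lost without tumor 312 or 313, the T cell call without 313 or 318, the erythroid call without 318, the mast cell call without 312, 303 or 313 and the platelet call without 307, 312, 303 or 318. The macrophage and platelet calls were also lost in the tumor channel alone, the platelet call with all 6 arrays above background and the erythroid call with no filter on dim probes.

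The lists of hypoxia, glycolysis and interferon genes were called lower at day 15 only with camera's preset correlation. Of 32 hypoxia and glycolysis genes, 28 were lower (median -0.42, camera adjusted p 1.9e-09, but adjusted p = 0.678 with an estimated correlation), among them the glycolytic enzyme genes Eno1 (-0.73) and Pgk1 (-0.91) and Pdk1 (-0.76), a kinase that holds back pyruvate dehydrogenase. Type I interferon response genes were lower in 26 of 30 (median -0.41, camera adjusted p 1.8e-07, but adjusted p = 0.678 with an estimated correlation), with Ifit2 at -1.17 and Usp18 at -1.01. Interferon-gamma response genes and chemokines were lower in 16 of 21 (median -0.49, camera adjusted p 8.2e-04, but adjusted p = 0.678 with an estimated correlation), with Cd274, which encodes PD-L1, at -0.69. In each of these lists 0 genes passed over all genes and 0 when adjusted over the list alone. Medians per tumor overlapped between the days in each list. In hypoxia and glycolysis genes, day 10 tumor 312 (0.71) lay below day 15 tumor 313 (1.27). In type I interferon genes, day 10 tumor 312 (2.60) was the lowest of all tumors. In interferon-gamma genes, day 15 tumor 318 (4.72) was the highest of all. The interferon-gamma call was lost without tumor 313 and after median centring, and Eno1, whose probe lay in the lost area of tumor 312, was higher in the tumor channel alone.

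The other 17 lists did not pass. NK and cytotoxic lymphocyte genes were lower in 12 of 21 (median -0.06, camera adjusted p 0.0651), with the granzyme gene Gzma at -1.37 and Klrb1c (NK1.1) at -1.40, neither of which passed. This list was called lower without background correction, without tumor 313 or 318, in the tumor channel alone, with the lost area left out and with the mean of all probes. Hepatocyte and hepatoma genes had a median change of -0.47 that became +0.35 without tumor 313. There the list was called higher (camera adjusted p 8.0e-06), as were liver metabolic enzymes and cell cycle genes. Cell cycle genes were called lower without tumor 307 or 318. After median centring, with all tumors, the hepatocyte and liver enzyme lists were also called higher, among 15 lists higher and 6 lower. Cholesterol synthesis and immediate early genes were each called higher in some settings, such as without tumor 313. Among 16 dendritic cell genes, Cd83 (+1.01) passed when adjusted over the list alone and none over all genes.

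**Figure D5:**
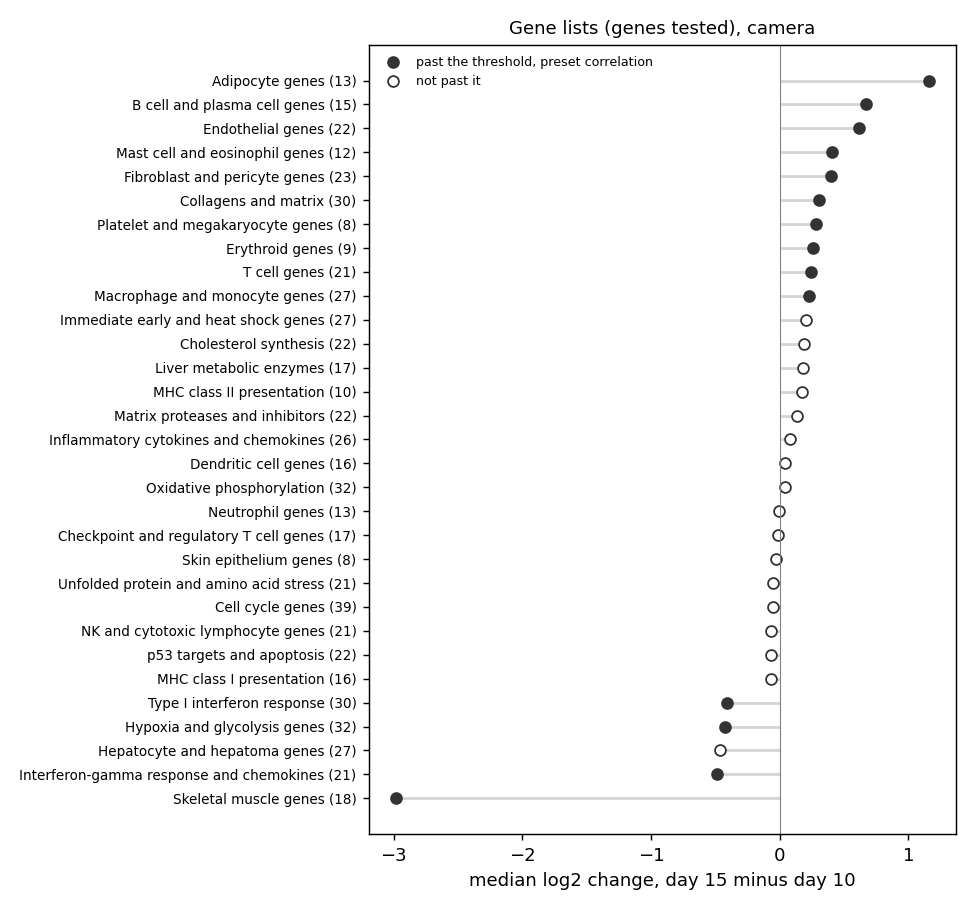
Median log2 change of day 15 minus day 10 for each of 31 gene lists (horizontal axis), with the number of genes tested in brackets. Filled points are the 10 higher and 4 lower lists past the threshold with camera's preset correlation; with an estimated correlation 0 passed.

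The reference signal was compared between the slides, which carried the days. Of 20915 probes, 0 differed by limma with Benjamini-Hochberg adjustment (275 unadjusted), and 0 after median scaling (594 unadjusted). Without tumor 312, with its lost area, 1 probe differed (1458 unadjusted), without 302 it was 1 (1462 unadjusted) and without 307 it was 4 (238 unadjusted). Among the unadjusted differences were 6 of the 7 muscle genes that fell. This check concerns hybridisation, scanning and the reference RNA; it says nothing of how the tumor RNA of the days was handled, where slide and day cannot be told apart.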

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

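The tests of an array fault in tumor 313, of exchanged dyes, of the genes richer in the reference, of the loss of signal in both dyes and of the slides were chosen after the result was seen, and the verdict rules of the tests on regenerating muscle and on epithelial genes were changed then to leave both undecided. The other tests of this part were written before their outcome was known. A lone array among 6 was looked for in 60 measures, and 11 were found. Chance gives about 1 in 20 for a single measure, but these measures are not independent of each other. Several rest on the lost area of tumor 312, and others had the same value on every array. The count is therefore not evidence against chance. The array of tumor 312 stood alone in its area of lost signal (13.9% of spots, 0 on the others), its mean Cy3 correlation with the other arrays (0.829, others from 0.960), its median Cy3 signal (167.6, others from 204.3), S100a9 (2.80, others from 5.20) and Cd8b1 (0.11, others from 6.02). Within the area the deviations of both dyes correlated at 0.916 over spots, and outside it the lowest Cy3 correlation lay -0.00976 from the lowest among the other arrays. Tumor 318 stood alone in Eprn (-4.06), Rhox5 (-3.92) and the median of erythroid genes against the reference (0.71, others up to 0.12). Tumor 313 stood alone in Ambp (-0.99), F2 (0.15) and Perp (-5.44, others from -3.37).

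The low liver genes of tumor 313 were weighed first. A fault of its array that reaches both dyes was argued against: its lowest Cy3 correlation, with tumor 312 left out, lay -0.00068 from the lowest among the others. A fault of the Cy5 label or of the tumor RNA alone could not be seen in Cy3. Few hepatoma cells in this sample is a possible explanation that stays open. Of 15 further hepatoma genes, 11 (73.3%) were lowest there, between the bounds of 80% and 50% set for it. A set of 89 genes richer in the reference moved by a median of -0.51, which bears on it only if hepatoma cells supply those genes. The set was drawn from genes well above background in all 6 tumors. Genes that fell to background in tumor 313 were thus left out, so this median cannot argue against few hepatoma cells. Loss of liver genes by hepatoma cells that stayed also remains open. Of 7 usable epithelial genes outside liver differentiation, 1 (14.3%) was lowest there, which met the bound set beforehand, but over all 22 tested genes 15 were lowest there (14 of the 15 not usable), and the verdict was withheld after the result was seen.

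The lower muscle genes of day 15 were weighed next. Muscle in a single tumor was argued against, since the median change stayed at -2.71 or beyond with each tumor left out in turn. Skeletal muscle taken along with the day 10 tumors could explain the pattern but was left open. Of 18 tested genes of another muscle list, 10 (55.6%) were lower by 1 or more, between the bounds of 80% and 50%. By any amount, 16 of the 18 were lower (median -1.55), with 9 passing when adjusted over the list alone and 0 over all genes. Of genes of developing and regenerating muscle, 0% were lower by 1 or more, which met the bound set against regenerating fibres; only 4 of 13 had enough signal to test, and Myh8, which regenerating fibres express, fell, so that after the result was seen this was left open too. Growth of the tumor between the days, the difference the design names, was not tested, and slide and day cannot be told apart.

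The neutrophil and other leukocyte genes that were scarce in the reference labelled blood were weighed last. An exchange of tumor and reference RNA between the dyes was argued against, since 3.33% of collagen and matrix genes were higher in Cy3. RNA of cells other than blood in the reference channel may account for the pattern but stays open. Of 60 probes of abundant blood cell genes, 38 (63.3%) were well above background in Cy3 on all 6 arrays, between the bounds of 50% and 80%, against 42.9% of all probes. Tumor exceeded the reference in 34 of 37 of these genes, with a median of 3.54. The test counted probes above background and did not weigh amounts. Outside it, Hbb-bt and Hba-a1 were higher in tumor by 5.80 and 3.76, though well above background in Cy3 on all 6 arrays. In tumor 313, Afp (-4.75), Foxa2 (-5.71) and Alb (-2.48) were richer in the reference, genes chosen after their values were seen. In the other 5 tumors Afp and Alb were higher in tumor.

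The 3 against 3 arrays make 10 splits, too few for a share under 0.05. The real split gave 10 probes past the threshold and the highest other 0, so that 1 split of the 10 reached that number, also with the lost area left out (1 split, highest other 0). For gene lists the real split gave 14 and the highest other 17, and 4 splits, the real one included, gave as many. In the Cy3 channel, the most probes past the threshold between the slides, with all arrays or with 1 left out, was 4.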

How the results depend on the processing

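Leaving out the area of lost signal was chosen after seeing the data; the other alternatives were planned. Of 18 moved counts outside the leave-one-out fits, those of genes higher at day 15 (2) were 1 after median centring, with processed signals, with the value table and with all 6 arrays above background, and 0 in the tumor channel alone and with the position block. Genes lower (7) were 0 with all 6 arrays above background, where the muscle genes were not tested, 0 in the tumor channel alone and 4 with the position block. Genes higher than the reference (4157) were 7924 and genes lower (1593) 5226 with no minimum ratio; genes lower were 4587 after median centring, 3232 with processed signals and 3230 with the value table. With an estimated correlation 0 lists were higher and 0 lower; with fry 0 were higher and 1 lower. Leaving out 1 tumor gave 0 to 6 genes higher at day 15, 3 to 24 lower and 0 to 4 probes differing in the reference channel. The cause was not tested, other than by fewer genes or arrays.

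With the lost area left out, the counts of 2 and 7 genes held and all 9 genes were shared. Processed signals shared 3 of the 9 genes, as did the value table; both called the muscle genes Ckm, Pvalb, Sln and Trdn instead. Median centring shifted the median of all genes by -0.30, and values are relative to that shift. List medians reversed for hepatocyte genes without 313 (-0.99 to 0.35 with 1 tumor left out), cell cycle genes without 313 (-0.32 to 0.30), inflammatory genes without 312 (-0.14 to 0.14), and neutrophil (0.10) and oxidative phosphorylation genes (-0.0627) after median centring; the cause was not tested. Of named genes between the days, 27 values lost their call in planned settings and 20 with 1 tumor left out; 7 and 3 values of genes without a call changed sign, among them Eno1 in the tumor channel alone. No paired analysis was possible because the days share no tumor numbers, and the slide block was not run because each slide held 1 day. Signal over background limits dim genes, which fall to a bound.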

Other observations

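The Ly49, immunoglobulin and clock genes described here were picked after their values were seen. The test of the clock by Arntl was chosen then too, while the tests on further clock genes and on single tumors were written before. The immunoglobulin genes, a family not tested as a list, had higher values at day 15, though 1 of them passed. All 24 tested immunoglobulin genes had higher values (median +1.74), 18 of them with values of the days apart where chance gives 10%. Of these, 16 passed without adjustment, 12 when adjusted over the list alone and 1, Igkv14-111, over all genes by limma with Benjamini-Hochberg adjustment. The heavy chain gene Ighg was higher by 2.40 (SE 0.58) and the light chain gene Igkv2-116 by 2.22 (SE 0.54), while Ighm, the IgM heavy chain, differed by 0.48 (SE 0.36). All 24 were higher under each scaling alternative, and 23 of 24 in the tumor channel alone. Related variable genes can share probes, so members are not separate evidence.

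The Ly49 receptor genes had lower values, though none passed over all genes and the fixed NK list was not called. All 15 tested Ly49 receptor genes (Klra), which encode receptors for MHC class I on NK cells, had lower values at day 15 under every scaling alternative (median -1.41). Of these, 13 had values of the days apart, where chance gives 10%. Without adjustment 14 passed, 14 when adjusted over the list alone and 0 over all genes by limma. Klra13-ps among them is named as a pseudogene. Whether the probes of these related genes share signal was not tested, so members are not separate evidence. Klra1 was lower by 1.80, as a change of -1.80 (SE 0.28), and Klra9 by a change of -1.65 (SE 0.25). Without tumor 313, Klra1, Klra15 and Klra16 passed over all genes.

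Clock genes, none of which passed over all genes, had values at the days in a pattern that may reflect another hour of the day at removal, which the labels do not give. Arntl, the activator of the clock, was higher at day 15 (+1.45, SE 0.17), while Nr1d1 (-1.36), Nr1d2 (-1.55) and Tef (-1.55), which peak opposite to it, were lower; none passed over all genes by limma. Of 10 tested clock genes not looked at before, 8 (80%) moved the way a shift of phase predicts, just at the bound of 80% set for it, with Dbp at -1.61 (SE 0.44). Without tumor 318 it was 6 of 10 (60%), the bound set against it, so the hour of removal was left open after that was seen. With the lost area of tumor 312, where both lay, left out, Arntl was at +1.41 and Dbp at -2.03. Less muscle at day 15 stays open, since its test used Arntl (1.45), a gene by which the pattern was found. A single tumor was argued against, since the smallest mean change with 1 tumor left out was 0.868 of that over all tumors, and 0.738 over the 10 genes not looked at before. The hour of removal, the slide and the day cannot be told apart in this design.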
